A study of Homo sapiens with 13 samples.

How the data were processed

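RNA was measured in HT1080 cells, a human fibrosarcoma cell line, after 6 h with trabectedin (labelled 4 µg/ml, a unit that is in doubt), doxorubicin (0.25 µg/ml) or mafosfamide (1.5 µg/ml). Each drug was given alone, with TRD (250 µmol/l), with TRAIL (50 ng/ml) or with both. Trabectedin is an alkylating agent that binds the minor groove of DNA, doxorubicin is an anthracycline that poisons topoisomerase II, and mafosfamide is an analogue of cyclophosphamide that needs no activation in the liver. TRAIL is a ligand of the death receptors TNFRSF10A and TNFRSF10B. The labels do not spell out TRD, and taurolidine, which the series design names, is an inference. There were 13 samples, 12 drug-treated and 1 control, with 1 sample per combination and therefore no replicate of any combination.

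Per the labels' protocols, 100 ng of total RNA was labelled with Cy3 and hybridised to Agilent whole-genome arrays. Per the file headers, intensities were read with Agilent Feature Extraction 10.7.3.1 under a protocol for 2 colours. The deposited values are processed intensities of 1 scan channel, from which the software had subtracted background, removed spatial trends and normalised the dye against the other channel, per the file headers. The deposited values were not normalised between arrays. The deposited table of values equalled these processed intensities in all 585195 cells, so that table gave no separate alternative.

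The file headers placed the samples on 3 slides. Slide 1 held the samples labelled trabectedin, trabectedin+TRD and trabectedin+TRAIL. Slide 2 held those labelled trabectedin+TRD+TRAIL, mafosfamide, mafosfamide+TRD and mafosfamide+TRAIL. Slide 3 held the control, the 4 doxorubicin samples and the sample labelled mafosfamide+TRD+TRAIL. On slide 3 a single array gave a sample from each of its channels, so 3 arrays carried 6 samples, although the labels give Cy3 for all. Which channel a sample came from was inferred from its dye normalisation factor. The sample with the larger factor on each shared array was taken as read in the same channel. Below, an array means the signal of 1 sample.

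Each array held 43376 spots other than controls, for 41000 distinct probes. The files gave no gene symbols, so 26386 probes were named through their RefSeq accessions and a gene table of assembly GRCh38.p14, for 17770 symbols. The scan grid was annotated to another build, so no coordinates are given. Before any analysis, 64 probes were left out by a rule on sex-linked genes. Of the listed symbols, 3 matched no single current symbol.

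Spots were averaged per probe and taken to log2, and the 75th percentile of each array was subtracted. The probe with the highest mean stood for each gene. Genes and unnamed probes well above background on at least 3 of the 12 treated arrays were kept, 25043 in all, of which 15446 had a symbol. limma 3.58.1 in R 4.3.3 fitted drug, TRD and TRAIL as additive terms to the 12 treated arrays with 7 residual degrees of freedom. Interactions were fitted as added terms. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Since the arrays of a term differ in their other treatments, the p-values measure the spread that the additive terms leave, which includes the slide.

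The tests covered 22 gene lists with camera (preset correlation 0.01), and again with an estimated correlation and with fry. The control array was compared without a test, since it was single: genes at least 2-fold apart were counted, and the median of a list was ranked among 10000 random lists matched on expression in 20 bins. All comparisons with the control share that array, so no overlap between them is given.

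The gene lists, the fits, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per contrast, the 10 largest rises and 10 largest falls that passed and had 1 sign in every matched pair of arrays, or the 3 smallest p-values where none passed. It added up to 4 passing members of each called list, 5 genes per interaction, the 8 highest and 8 lowest genes per drug against the control, and 11 fixed genes of TRAIL signalling and stress. Genes of the doxorubicin pairs, the marker genes and the genes of each shared array were chosen after their values were seen. Some of the genes chosen in these ways are not reported here.

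Alternatives were normexp background correction (offset 50), quantile normalisation, the median of each array, other filters, the mean of all probes, slide as a fixed or random block, the variance trend, treatment pairs, the control in the fit, and leaving out each array. normexp used the median signal, since the files hold no mean signal. camera was not run with slide as a random block. The counts with slide and channel as a block, those of the doxorubicin arrays alone and those of the doxorubicin pairs were added after seeing the data.

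The fits were tested on simulated data drawn from the fitted levels and residual spread, with 200 changed genes, 50 at each size. For TRD, 22 of 50 genes changed 2-fold and 49 of 50 changed 32-fold were recovered. For TRAIL these were 14 and 47 of 50. False calls numbered 15 for TRD and 11 for TRAIL. The simulated spread was independent between arrays, while the real arrays correlate within slides (0.888). These rates therefore do not give the power of the real tests. With the 4 doxorubicin arrays alone, 0 of 50 were recovered at either size, so a count of 0 there carries no information. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. The number of arrays limits the precision.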

Results

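The series asked how TRD and TRAIL alter the response of fibrosarcoma cells to 3 cytotoxic drugs. Gene expression was measured on 13 arrays. Between 69.0% and 75.5% of the 43376 spots lay well above background. Expression values below are log2 signals relative to the 75th percentile of the array. No combination was replicated, so errors are those of the additive fit over 12 treated arrays.

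The arrays fell into blocks by slide. Across genes, which are not independent replicates, the correlation was 0.976 to 0.995 for 24 pairs on the same slide and 0.793 to 0.866 for 54 pairs on different slides. Pairs with the same drug on different slides reached 0.849 to 0.865, below the 0.976 to 0.992 of pairs on 1 slide that differed in drug or were compared with the control. EPCAM, an epithelial adhesion molecule, stood at 3.85 to 6.41 on the 7 arrays of slides 1 and 2 and at -8.64 to -7.69 on the 6 arrays of slide 3. KRT19, an epithelial keratin, stood at 6.99 to 8.21 and at -3.81 to -3.32. PTX3 stood at -5.80 to -4.95 on slides 1 and 2 and at 2.81 to 3.98 on slide 3. VIM, a mesenchymal intermediate filament protein, stood at 1.97 to 4.81 and at 6.88 to 7.47. THY1, also a gene of mesenchymal cells, went the other way, at 3.0 to 4.35 on slides 1 and 2 and at 1.28 to 1.86 on slide 3. The array labelled mafosfamide+TRD+TRAIL, on slide 3, had EPCAM at -7.69, near the control at -8.12. The array labelled trabectedin+TRD+TRAIL, on slide 2, had EPCAM at 3.94 and CDH1 at -3.07, against 5.02 to 5.19 for CDH1 on the trabectedin arrays of slide 1. The epithelial genes of slides 1 and 2 go against the label of a mesenchymal line, so samples are called by their label throughout.

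**Figure D1:**
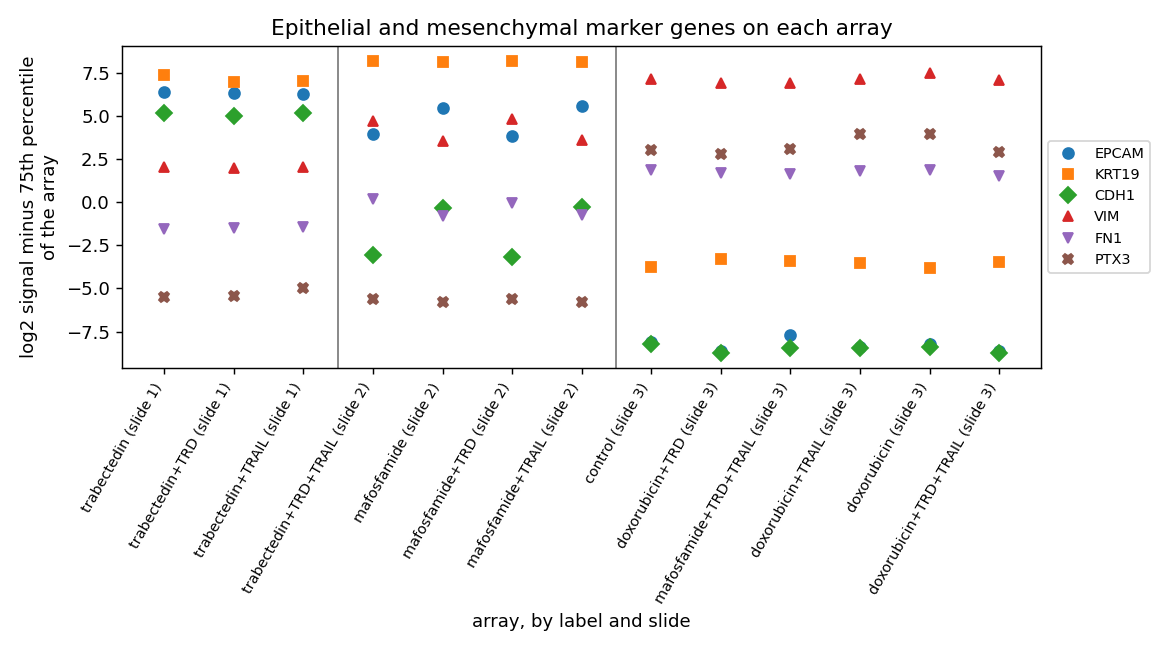
Log2 signal minus the 75th percentile of the array (vertical axis) for 3 epithelial genes (EPCAM, KRT19, CDH1) and 3 genes of mesenchymal cells (VIM, FN1, PTX3) on each of the 13 arrays, ordered by slide, with vertical lines between slides. EPCAM lies at 3.85 or above on slides 1 and 2 and at -7.69 or below on slide 3.

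Trabectedin and doxorubicin were compared to ask how the responses to the drugs differ. The largest rises on the trabectedin arrays were those of EPCAM (log2 difference 14.20 ± 2.16 SE, at least 14019.5-fold), KRT23 (13.18) and TMEM45B (13.03). DUSP23 (12.65), the actin-bundling protein gene VIL1 (12.21), LAD1 (12.18), SELENBP1 (12.14), TSPAN8 (11.84), the fatty acid binding protein gene FABP1 (11.78) and PLBD1 (11.74) followed. Genes lower on the trabectedin arrays were GNB4 (-10.08), CEP15 (-8.81), PTX3 (-8.79), the growth factor gene TGFB2 (-8.72), ARMCX1 (-8.63), the transcription factor gene FLI1 (-8.46), PDGFC (-8.41), GSDME (-8.40), ANTXR1 (-8.35) and BCAT1 (-8.27). All 10 of the higher genes, and GNB4, CEP15, ARMCX1, FLI1 and GSDME, lay below background on the lower side, so the differences are no exact sizes: VIL1 was at least 2869-fold higher and GNB4 at least 1053-fold lower. The same limit holds for TGFB2, below background on 3 of the 4 trabectedin arrays, and for PDGFC and ANTXR1, below it on 2. FABP1 and TSPAN8 lay below background on the array labelled trabectedin+TRD+TRAIL too, so their differences come from the 3 arrays of slide 1. In all, 8896 genes were higher and 5209 lower of 25043 tested by limma. With normexp these counts were 12442 and 4743, with quantile normalisation 6835 and 6373, and with the median of each array 7133 and 6896. All 4 trabectedin arrays lie on slides 1 and 2 and all 4 doxorubicin arrays on slide 3, so the unblocked comparison follows the slides. When blocked by slide it rests on the 2 arrays whose drug spans slides, and 0 genes passed.

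Between these arrays 9 gene lists passed in camera with the preset correlation, and 5 with slide as a block. None passed with an estimated correlation (adjusted p = 0.466 for 8 lists and 0.515 for the interferon response genes). With slide as a block many members named below turned sign, such as CCNE2 (0.90), CCNA2 (0.54), SPARC (2.85), HSPA1A (2.22) and IRF7 (-0.70). Others, such as S100A4 and CENPE, kept theirs. The directions below are those without the block, which the 5 lists need not keep. Among 15 measured markers of other cell types, 12 were higher and 0 lower with trabectedin, with CDH1 at least 2226-fold higher, KRT19 at 10.91 and the leukocyte gene PTPRC at 4.07. Adjusted over the list alone, 12 passed. Of 22 extracellular matrix and mesenchymal genes, 16 were lower and 2 higher (18 adjusted over the list alone): LOX, a collagen crosslinking enzyme, at -5.99, the matrix protein gene SPARC at -5.06 and MMP3, at least 53.5-fold lower, against S100A4 at 9.48. Of 26 DNA replication genes 14 were lower (14 adjusted over the list alone), including CCNE2 (-3.14), PRIM1 (-2.12), RRM2 (-2.09) and CDC45 (-2.08). Of 22 G2/M genes 15 were lower (15 adjusted over the list alone), including CCNA2 (-1.82), CENPE (-1.57), PLK1 (-1.31) and KIF11 (-1.22). Of 31 p53 target genes 13 were lower and 2 higher (15 adjusted over the list alone), with PMAIP1 at -3.54, PLK2 at -3.32, MDM2 at -3.15 and GADD45A at -2.02. Heat shock genes had 12 of 19 lower and 3 higher (15 adjusted over the list alone), with HSPA1A at -3.83, SERPINH1 at -2.54 and CHORDC1 at -2.13 against HSPB1 at 7.59. Hypoxia and glycolysis genes had 11 of 19 lower and 3 higher (15 adjusted over the list alone), with BNIP3 at -7.23 and ENO2 at -3.75 against ADM at 5.97 and EGLN3 at 3.49. Metallothionein genes had 9 of 12 lower and 2 higher (11 adjusted over the list alone), with MT1E at -3.43, MT2A at -3.33 and MT1B at -3.31 against MT1F at 5.28. Interferon response genes had 8 of 16 higher and 0 lower (8 adjusted over the list alone), with CXCL11 below background on the doxorubicin arrays, IRF7 at 7.66, OAS1 at 4.23 and IFI6 at 4.15. CCNE2, EGLN3, IRF7 and PTPRC lay below background on some arrays of their lower side. Among the fixed genes, TNFRSF10A was at least 89.5-fold higher with trabectedin (log2 difference 6.99), CASP8 (2.43) and CFLAR (2.14) were higher and TNFRSF10B (-1.64) lower, all past the threshold. With slide as a block TNFRSF10A (-0.81), CASP8 (-0.41) and CFLAR (-0.68) turned sign, and TNFRSF10B did not. CDKN1A (-0.68), ATF3 (-1.69), DDIT3 (-0.15), HMOX1 (-0.25), FOS (0.99) and JUN (-0.83) did not pass.

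Trabectedin and mafosfamide arrays were compared next. FABP1 (11.49), OLFM4 (10.01), AGR2 (9.63), STYXL2 (8.80), FAM3D (8.66), TSPAN8 (8.63), ALOX5 (8.58), SOD3 (8.56), REG4 (8.40) and BTNL3 (7.98) were higher with trabectedin. HDGFL3 (-6.21), the actin-binding protein gene CALD1 (-5.64), LHFPL6 (-5.60), ANTXR1 (-5.29), INHBB (-5.13), HTRA3 (-5.04), GNG11 (-4.88), EGR2 (-4.83), RBMS1 (-4.77) and MSN (-4.75) were lower. FABP1, OLFM4, AGR2, STYXL2, ALOX5 and BTNL3 lay below background on the mafosfamide arrays and on the array labelled trabectedin+TRD+TRAIL, so their differences come from the 3 arrays of slide 1. TSPAN8 lay below background on that array and on 2 mafosfamide arrays, FAM3D on 2 and REG4 on 1 of the latter. HDGFL3, LHFPL6, HTRA3 and EGR2 lay below it on 3 of the 4 trabectedin arrays and ANTXR1 on 2, so none of these differences is an exact size. In all, 3596 genes were higher and 1744 lower of 25043. With quantile normalisation these counts were 2524 and 2110, with the median of each array 2421 and 2302. With slide as a block 1 gene passed. Leaving out 1 array moved the count by over 1.5 times in 10 of 12 cases, and it ranged from 0 without the array labelled trabectedin to 12136 without the array labelled trabectedin+TRD+TRAIL.

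Of the 22 lists, 11 passed between trabectedin and mafosfamide, and 7 with slide as a block. None of the 11 passed with an estimated correlation (adjusted p = 0.206 for the immediate early genes and 0.435 or above for the others). With slide as a block many members named below turned sign, such as RRM2 (0.30), CCNA2 (0.37), SERPINH1 (0.0675), MT1E (0.0535) and CXCL11 (-1.97). Others, such as EGR2 and DDIT3, kept theirs. The directions below are those without the block. Immediate early genes, which respond to growth signals and stress, had 7 of 26 lower (8 adjusted over the list alone), with EGR2 at -4.83, FOSL1 at -2.61, CCN1 at -2.59 and EGR1 at -2.43. ATF4 target genes had 6 of 20 lower and 1 higher (9 adjusted over the list alone), with STC2 at -2.15, DDIT3 at -2.09 and PSAT1 at -1.99 against NUPR1 at 4.48. Metallothionein genes had 8 of 12 lower (9 adjusted over the list alone), with MT1M at -3.73, MT1E at -3.56, MT1B at -3.31 and MT2A at -2.95. DNA replication genes had 7 of 26 lower (20 adjusted over the list alone), including RRM2 (-2.41), E2F1 (-2.28), PRIM1 (-1.93) and MCM4 (-1.90). G2/M genes had 4 of 22 lower (12 adjusted over the list alone), these being CCNA2 (-1.22), TPX2 (-1.06), KIF20A (-0.92) and CENPE (-0.86). Heat shock genes had 6 of 19 lower and 1 higher (8 adjusted over the list alone), with HSPA1A at -3.87, SERPINH1 at -2.17, HSPH1 at -1.57 and CHORDC1 at -1.46. Hypoxia and glycolysis genes had 6 of 19 lower (7 adjusted over the list alone), with ANKRD37 at -3.75, ENO2 at -3.60, PDK1 at -1.41 and LDHA at -1.34. Extracellular matrix genes had 2 of 22 lower and 1 higher (3 adjusted over the list alone), with COL6A1 at -2.47 and THY1 at 1.22. Interferon response genes had 7 of 16 higher (9 adjusted over the list alone), with CXCL11 at 6.57, OASL at 3.70, IFI6 at 3.05 and MX1 at 2.70. Aldehyde dehydrogenase and glutathione transferase genes had 7 of 15 higher (8 adjusted over the list alone), with ALDH1A1 at 7.18, GSTA1 (below background on the mafosfamide arrays), GSTM2 at 2.504 and GSTA4 at 2.07. Ribosomal protein genes had 5 of 24 higher (8 adjusted over the list alone), including RPL7 (1.09), RPL30 (1.03), RPL8 (0.69) and RPL3 (0.66). ALDH1A1 and CXCL11 lay below background on 3 of the 4 mafosfamide arrays. Of the fixed genes DDIT3 passed, and TNFRSF10A (1.12), TNFRSF10B (-0.27), CASP8 (1.18), CFLAR (0.53), CDKN1A (-0.25), MDM2 (-0.07), ATF3 (-1.74), HMOX1 (1.24), FOS (-1.09) and JUN (-0.97) did not.

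Doxorubicin and mafosfamide arrays were compared last. KRT23 (-10.701), EPCAM (-10.28), TMEM45B (-9.81), BMP7 (-9.59), KRT19 (-8.79), TRIM15 (-8.76), ASCL2 (-8.42) and SYK (-8.32) were lower with doxorubicin. GNB4 (8.42), BCAT1 (7.51), BNIP3 (7.09), CEP15 (6.64), SCG5 (6.57), GPC6 (6.51), MAP9 (6.51), MDFIC (6.47), CCBE1 (6.45) and GSDME (6.45) were higher. KRT23, EPCAM, TMEM45B, TRIM15 and SYK lay below background on the doxorubicin arrays, BMP7 on 3 of them and ASCL2 on 1, and the first 4 of these also on the array labelled mafosfamide+TRD+TRAIL. GNB4, CEP15, SCG5, MAP9, MDFIC, CCBE1 and GSDME lay below it on the 3 mafosfamide arrays of slide 2 and GPC6 on 2, so none of these differences is an exact size. Of 25043 genes 1814 were higher and 2928 lower. With normexp these counts were 3069 and 9625, with quantile normalisation 1793 and 1654, and with the median of each array 2179 and 2320. With slide as a block 0 passed. Leaving out 1 array moved the count by over 1.5 times in 11 of 12 cases, from 3 without the array labelled mafosfamide to 12909 without the array labelled mafosfamide+TRD+TRAIL, which shares slide 3 with the doxorubicin arrays.

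Between doxorubicin and mafosfamide 5 lists passed, and none with an estimated correlation (adjusted p = 0.747 to 0.825). p53 target genes had 7 of 31 higher and 0 lower (7 adjusted over the list alone), with MDM2 at 3.09, SESN1 at 2.84, POLH at 2.73 and RRM2B at 2.01. Extracellular matrix and mesenchymal genes had 12 of 22 higher and 2 lower (15 adjusted over the list alone), with MMP3 at 4.49 (below background on 3 of the 4 mafosfamide arrays), LOX at 4.43 and MMP1 at 4.05 against S100A4 at -6.69. Markers of other cell types had 6 of 15 lower (11 adjusted over the list alone), including EPCAM, KRT19, CDH1 (below background on the doxorubicin arrays) and KRT8 (-2.36). Cholesterol synthesis genes had 4 of 19 lower (7 adjusted over the list alone), among them CYP51A1 (-1.12), INSIG1 (-0.996) and SQLE (-0.93). Ribosomal protein genes passed as a list with a median of 0.28 and 0 of 24 members past the threshold (0 adjusted over the list alone). Among the fixed genes TNFRSF10A (below background on the doxorubicin arrays), CFLAR (-1.61) and DDIT3 (-1.94) were lower and MDM2 higher. With slide as a block TNFRSF10A (0.23), CFLAR (0.15) and, of the matrix genes, MMP3 (-0.48) turned sign, while DDIT3 and MDM2 kept theirs. The directions in this comparison are those without the block. TNFRSF10B (1.36), CASP8 (-1.25), CDKN1A (0.43), ATF3 (-0.05), HMOX1 (1.49), FOS (-2.09) and JUN (-0.14) did not pass.

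TRD was compared over 6 matched pairs of arrays, and no gene passed. In 2 of these pairs the arrays lie on different slides, with 9983 and 10467 genes at least 2-fold apart, against 1064 to 2721 in the 4 pairs on 1 slide. The smallest p-values, none past the threshold, belonged to MSX2P1 (-1.28 ± 0.21 SE), SERTAD3 (-0.998) and the receptor gene NOTCH1 (-1.12), each lower with TRD in 6 of 6 pairs at an adjusted p = 0.808. FOS stood at 1.41 ± 0.65 and was higher in 5 of 6 pairs (adjusted p = 0.808). TNFRSF10A (-1.27), TNFRSF10B (0.37), CASP8 (-0.48), CFLAR (-0.18), CDKN1A (-0.49), MDM2 (0.01), ATF3 (-0.09), DDIT3 (0.29), HMOX1 (-0.39) and JUN (0.09) did not pass either. limma called 0 of 25043 genes, with 1349 at an unadjusted p under 0.05. With camera's preset correlation 10 lists passed, and 3 with slide as a block. None passed with an estimated correlation (adjusted p = 0.629), and 0 members of these lists passed, adjusted over the list alone or over all genes. Extracellular matrix genes (median 0.60), metallothionein genes (0.87), hypoxia genes (0.36), DNA replication genes (0.29), G2/M genes (0.25), immediate early genes (0.19) and heat shock genes (0.17) were higher in their median. Interferon response genes (-0.47), markers of other cell types (-0.26) and cholesterol synthesis genes (-0.17) were lower in their median.

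TRAIL was compared in the same way, with 2 of 6 pairs on different slides (9972 and 10157 genes at least 2-fold apart, against 518 to 1048 in the 4 pairs on 1 slide). OTUD7B (-0.56 ± 0.15 SE), ZNF880 (-0.63) and BCDIN3D (-0.55) had the smallest p-values, each lower in 6 of 6 pairs at an adjusted p = 0.993, which did not pass. Of the 2 probes of OTUD7B only 1 had that sign. TNFRSF10A (-1.22), TNFRSF10B (0.20), CASP8 (-0.38), CFLAR (-0.23), CDKN1A (0.06), MDM2 (0.30), ATF3 (0.83), DDIT3 (0.54), HMOX1 (-0.12), FOS (0.89) and JUN (0.55) did not pass. limma called 0 of 25043 genes, with 201 at an unadjusted p under 0.05. Immediate early genes had a median of 0.48 and were the list with the smallest camera p (adjusted p = 2.87e-06, or adjusted p = 0.158 with an estimated correlation). The other 11 lists that passed with the preset correlation had an adjusted p = 0.513 or above with an estimated correlation. Extracellular matrix genes (0.51), metallothionein genes (0.64), DNA replication genes (0.25), hypoxia genes (0.25), ATF4 target genes (0.19), heat shock genes (0.18), G2/M genes (0.18) and p53 target genes (0.06) were higher. Aldehyde dehydrogenase and glutathione transferase genes (-0.50), markers of other cell types (-0.31) and interferon response genes (-0.31) were lower. In these 12 lists 0 members passed, adjusted over the list alone or over all genes, and with slide as a block 4 lists passed.

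Interactions asked whether the combination departs from its parts. limma called 0 genes for TRD with TRAIL (538 at an unadjusted p under 0.05), 0 for TRD between drugs (1092) and 0 for TRAIL between drugs (148). Leaving out 1 array gave up to 91, 3342 and 1474 genes. With slide as a block, TRD between drugs gave 858 genes, led by MAL2 and ANO4 (adjusted p = 0.00280 for both), then DCDC2, DKK4 and VIL1 (adjusted p = 0.00338 for all 3). These genes were chosen by the block fit after seeing the data, while the naming rule covered the unblocked test, in which none passed. VIL1, 1 of the epithelial genes that separate the slides, also differed within slide 2. It stood at -2.82 on the array labelled mafosfamide+TRD, at 1.93 on that labelled mafosfamide and at 1.91 on that labelled mafosfamide+TRAIL. In the trabectedin pair of slide 1 it stood at 5.41 with TRD and at 5.48 without.

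Within slides 1 and 2, 17 of 22 NF-kB target genes were at least 2-fold higher on the array labelled trabectedin+TRD than on that labelled trabectedin, and 19 of 22 on that labelled mafosfamide+TRD than on that labelled mafosfamide. The cytokine gene CCL20 was 8.40 higher on the array labelled trabectedin+TRD than on that labelled trabectedin, and 7.79 higher on that labelled trabectedin+TRAIL. TNFAIP3, a feedback inhibitor gene of NF-kB, was 5.63 and 5.74 higher, while CXCL8 lay below background with trabectedin alone. The list median was 2.62 and 2.67, above all random lists in both cases, but both comparisons share the array labelled trabectedin, and the median was 0.0405 between the other two. On slide 2 the median was 3.92 for mafosfamide+TRD and 3.38 for mafosfamide+TRAIL against mafosfamide alone, with BIRC3, an apoptosis inhibitor gene, at 7.55 and 5.84. Both of these share the array labelled mafosfamide, against which that labelled trabectedin+TRD+TRAIL had a median of 0.0512 for the list. Over all genes it lay nearer to mafosfamide+TRD (948 genes at least 2-fold apart) than to mafosfamide (2318). The arrays labelled mafosfamide+TRD and mafosfamide also differed in marker genes: SPARC stood at 3.65 and -1.35 and VIL1 at -2.82 and 1.93. KRT19 was nearly alike on them, at 8.21 and 8.10. The array labelled mafosfamide+TRAIL lay near mafosfamide in SPARC (-1.92) and VIL1 (1.91). The median of 3.92 thus cannot be ascribed to TRD alone. No p-value applies, since each comparison rests on 2 arrays.

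**Figure D2:**
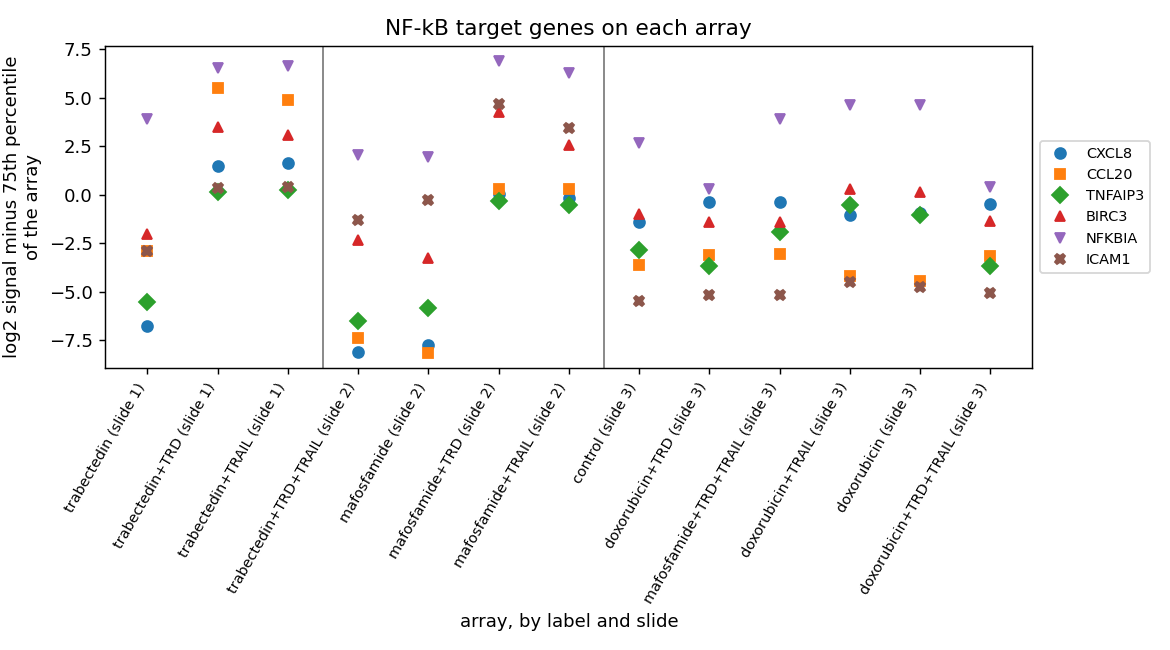
Log2 signal minus the 75th percentile of the array (vertical axis) for 6 NF-kB target genes on each of the 13 arrays, ordered by slide, with vertical lines between slides. On slides 1 and 2 the arrays labelled trabectedin+TRD, trabectedin+TRAIL, mafosfamide+TRD and mafosfamide+TRAIL stand above the others, with list medians of 2.62 to 3.92 against the drug alone. Points below background are CXCL8 with trabectedin, and CXCL8 and CCL20 with mafosfamide and with trabectedin+TRD+TRAIL, where TNFAIP3 is below it too.

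The control is a single array, so differences from it are given without a test. CXCR4, a chemokine receptor gene, was 3.95 higher with doxorubicin alone (15.4-fold), followed by the stress transcription factor gene ATF3 (2.58), JUNB (2.03), ANGEL1 (1.98), CPT1C (1.78), LCA5 (1.68), ID2 (1.68) and FOS (1.63). CXCR4 stood at -8.21 on the control, lower than EPCAM there (-8.12), which lay below background, so 15.4-fold is no exact size. STRIP2 (-2.38), SLC4A4 (-1.82), TNFAIP8L1 (-1.79), APOL6 (-1.69), MIRLET7BHG (-1.69), NRF1 (-1.69), PIF1 (-1.61) and RNF125 (-1.60) were lower. CDKN1A stood at 0.87 and MDM2 at 0.27, while TNFRSF10B (0.22), CASP8 (0.55), CFLAR (-0.12), DDIT3 (-0.45), HMOX1 (0.10) and JUN (-0.87) lay within 2-fold. TNFRSF10A was not above background on any slide-3 array. p53 target genes had a median of 0.44 and NF-kB target genes of 0.68. In all, 366 genes were at least 2-fold higher and 492 lower, on arrays of 1 slide. With normexp these were 62 and 62, and at 4-fold 145 and 102, which turns the balance.

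The trabectedin and mafosfamide arrays on slides 1 and 2 differed from the control in 10164 to 13936 genes, while the array labelled mafosfamide+TRD+TRAIL differed in 1684. SOD3 (12.37), ASCL2 (11.97), SECTM1 (11.68), SPINT2 (11.57), KRT19 (11.17), S100P (11.09), SPINK1 (10.92) and TFF3 (10.696) were higher with trabectedin alone. CALD1 (-8.79), PTX3 (-8.50), the glucocorticoid receptor gene NR3C1 (-8.29), CMTM3 (-8.29), TENM2 (-7.97), IL1B (-7.97) and BEX1 (-7.92) were lower. With mafosfamide alone KRT19 (11.88), ASCL2 (11.66), CXCR4 (10.701), SPINT2 (10.51), CCDC3 (9.91), TUBB2B (9.65), LIMS3 (9.65) and S100A4 (9.20) were higher. BCAT1 (-9.61), KIAA1549L (-8.58), PDGFC (-8.28), RBMS3 (-8.27), MAGEA1 (-8.16), AMIGO2 (-7.59), LYPD1 (-7.27) and RFTN1 (-7.18) were lower. SECTM1 and CXCR4 stood at -8.20 and -8.21 on the control, and RBMS3 at -8.41 with mafosfamide alone. Genes below background stood higher on these arrays, EPCAM at -8.12 on the control and FABP1 at -8.03 with mafosfamide. The differences of SECTM1, CXCR4 and RBMS3 are thus no exact sizes. The array labelled mafosfamide+TRD+TRAIL had FOS at 7.77, EGR1 at 7.14 and the heat shock gene HSPA6 at 6.13 above the control, and a median of 1.46 over immediate early genes.

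On the doxorubicin arrays, all on slide 3, 11 of 22 NF-kB target genes and 7 of 32 p53 target genes were at least 2-fold lower with TRD in both pairs. In camera over these 4 arrays, with 1 residual degree of freedom, both lists passed with the preset correlation (adjusted p = 1.05e-08 and 1.95e-09). In all, 6 lists passed for TRD. DNA replication (camera adjusted p = 0.00183), death receptor and apoptosis (0.00404) and NRF2 oxidative stress genes (0.0419) were lower, and histone genes (0.0419) higher. With an estimated correlation the adjusted p was 0.880 for the NF-kB and p53 lists. The estimates, 0.00395 and 0.0194, lay near the preset 0.01. That version rests on the 1 residual degree of freedom and called no list, so it decides nothing. NFKBIA, the inhibitor of NF-kB, was 4.33 lower without TRAIL and 4.21 lower with it. CSF2 (-4.62 and -2.57), the proapoptotic gene BCL2L11 (-3.44 and -3.41), NUAK2 (-3.54 and -3.06), TNFAIP3 (-2.61 and -3.12) and CCL2 (-2.96 and -2.74) were lower in both pairs. EGR1 (3.25 and 3.09), FOS (2.61 and 1.32) and RGS2 (1.96 and 1.71) were higher in both. Of the NF-kB target genes 1, CCL20, was higher in both, and the list medians were -0.94 and -0.93. The p53 target genes lower in both were BTG2, PLK3, PPM1D, SESN1, SESN2, TIGAR and TP53INP1, with list medians of -0.54 and -0.42. Over all genes 393 were lower and 90 higher in both pairs, while 188 were 2-fold apart in opposite directions. With normexp these counts were 142, 24 and 61, and at 4-fold 63, 9 and 106, more opposite than alike. For TRAIL 2 were lower and 3 higher in both pairs, with 183 opposite, and APOL6 (-1.09 and -1.10) was the named one among the lower genes. These pairs were examined after seeing the data.

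**Figure D3:**
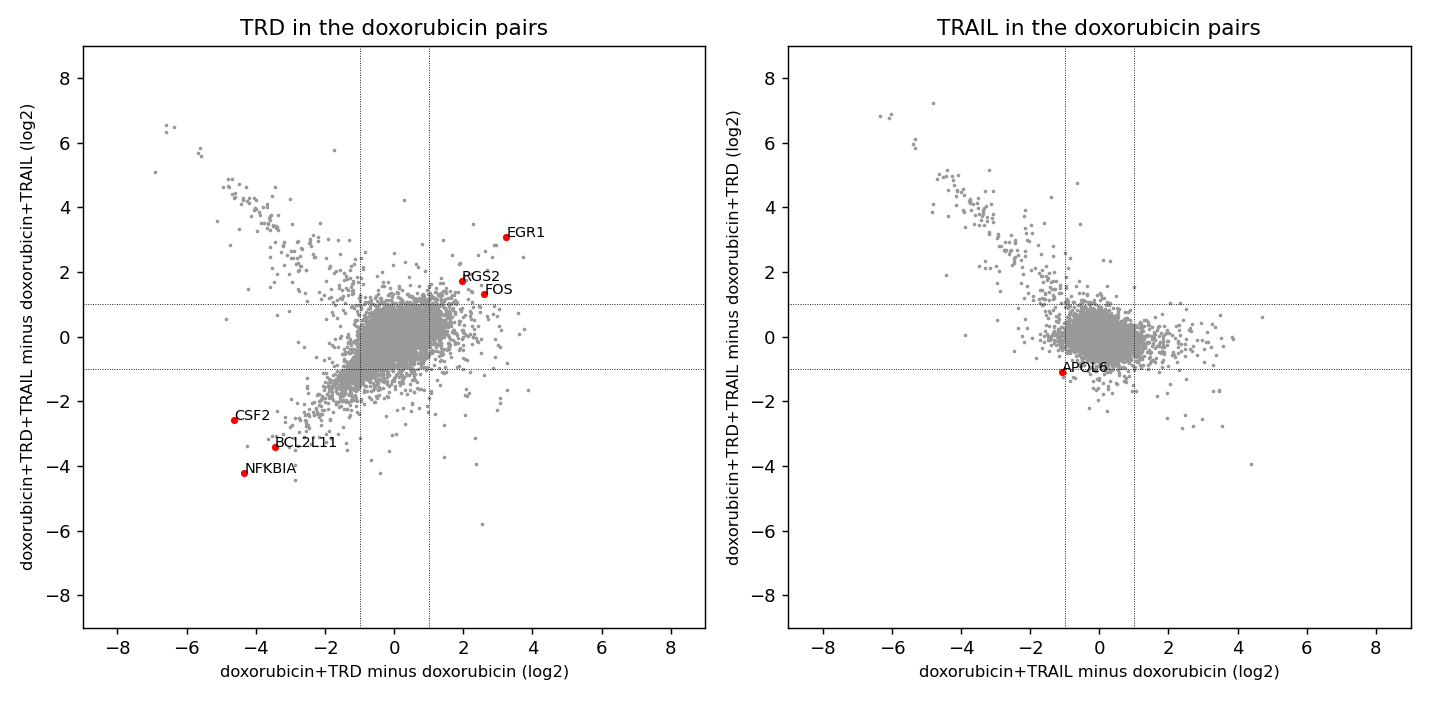
Log2 difference without (horizontal axis) against with (vertical axis) the other agent for TRD (left) and TRAIL (right) in the 2 doxorubicin pairs; each point is a gene and dotted lines mark 2-fold. For TRD 393 genes lie lower in both pairs and 90 higher, and 188 are 2-fold apart in opposite directions, against 183 for TRAIL.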

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

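The tests of the other splits, the marker genes, the measures compared within each drug and all the weighing tests of this part were run after the results were seen, and the threshold for the splits was set in advance. Within each drug's 4 arrays 6 measures were compared, except the share of features differing between channels for doxorubicin, where a pair of samples has 1 array and so 1 value, 17 comparisons in all, of which 7 had 1 array far from the other 3. Chance gives about 1 in 20, and the measures are not independent.

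Among the trabectedin arrays, the array labelled trabectedin+TRD+TRAIL stood apart with EPCAM at 3.94, VIM at 4.71 and FN1 at 0.16, and 40.9% of its features differed between the 2 scan channels. Among the mafosfamide arrays, the array labelled mafosfamide+TRD+TRAIL stood apart with EPCAM at -7.69 and KRT19 at -3.40, and 9.95% of its features differed between channels. The scan channel that the comparisons do not use differed from the deposited one in 46.0%, 45.5% and 45.2% of features on the arrays labelled trabectedin, trabectedin+TRD and trabectedin+TRAIL. The shares were 41.9%, 41.8% and 41.6% on those labelled mafosfamide, mafosfamide+TRD and mafosfamide+TRAIL. With slide as a block, limma called 858 genes whose difference with TRD differed between drugs.

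The first pattern is the epithelial markers on the 7 arrays of slides 1 and 2. An effect of mafosfamide on all 7 arrays is argued against by the trabectedin arrays, whose EPCAM lay at least 12.06 above the control, and one of trabectedin on all 7 by the mafosfamide arrays of slide 2, where it lay at least 11.97 above, sizes that are not exact since the control lay below background. Both values restate the pattern, which was already seen, and they count only if the labels hold. An effect of mafosfamide on its 3 arrays cannot be told apart from the slide, although EPCAM lay only 0.43 above the control on the array labelled mafosfamide+TRD+TRAIL, because that is 1 array with TRD and TRAIL as well. Dye normalisation is argued against, since without it EPCAM still differed by at least 6.92 between the slides. Added RNA of other cells stays open: 10 genes bright on all of slide 3 were undetected on all 7 arrays, too few to decide, and 53 such genes were at least 32-fold lower, a test chosen after that first one, and one that a drug could also meet. RNA of another source in the deposited channel or under the label stays open. At least 40.9% of features differed between channels there, but what the other channel held is not known, so this share decides nothing. On slide 3 both channels held samples of this series. No biological explanation beyond the drugs was tested. An effect of trabectedin on its own 4 arrays stays open, untested since all of them lie on these slides.

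The second pattern is the NF-kB target genes, higher on 4 arrays of slides 1 and 2. An effect of TRD with every drug is argued against by a median of -0.93 in the doxorubicin pair taken as read in 1 channel. One of TRAIL with every drug is argued against by a median of -0.0215 in such a pair. Both hold only if the labels do: where slides 1 and 2 carry RNA of another source, a slide-3 pair cannot test an effect there. Dye normalisation is argued against, since without it the smallest median was 1.83. Labels that do not match the arrays cannot be told apart from an effect of the combination, because the median was 4.02 between the arrays labelled mafosfamide+TRD and trabectedin+TRD+TRAIL. An effect that depends on the drug stays open, untested for want of replicates.

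The third pattern is the medians of NF-kB and p53 target genes, below 0 with TRD on the doxorubicin arrays. A difference between channels is argued against by the p53 median of -0.42 in the pair taken as read in 1 channel, if the inferred channels hold. Dye normalisation is argued against by a median of -0.31 nearest to 0 without it. Signal of the array shared by doxorubicin and doxorubicin+TRD+TRAIL moves the pairs in opposite directions. It is argued against by the 2 of 54 members of both lists with opposite signs. Doxorubicin+TRD shared its array with the control, and doxorubicin+TRAIL with mafosfamide+TRD+TRAIL. Signal of either of those arrays would move 1 pair alone, so the signs cannot test it, and it stays open. Over all genes the array shared by doxorubicin and doxorubicin+TRD+TRAIL stays open, with 106 genes 4-fold apart in opposite directions against 63 lower and 9 higher in both. An effect of TRD with every drug is argued against for NF-kB target genes, if the labels hold. Their median with TRD was 2.62 in the trabectedin pair and 3.92 in the mafosfamide pair on 1 slide. The arrays of that mafosfamide pair also differ in marker genes (SPARC 3.65 with TRD and -1.35 without). For p53 target genes an effect of TRD with every drug cannot be told apart from one with doxorubicin alone. Their medians in the trabectedin and mafosfamide pairs were -0.0943 and 0.0806. On the array labelled mafosfamide+TRD+TRAIL, which differs from the control in mafosfamide and TRAIL as well, the medians were 0.46 and -0.00959. Of the 393 genes lower in both pairs, 77.9% were also lower on it than on the control, against 43.8% of all genes. This comparison replaced one with the doxorubicin+TRAIL array (91.3% against 44.6%), because that array had served to choose the genes. An effect of TRD with doxorubicin stays open, untested for want of replicates.

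Other splits of the same arrays were counted. For TRD, for TRAIL and for their interaction the real count of genes was 0, which all 100 of 100 splits reach by construction, so the splits decide nothing there. The highest other counts were 4015, 4353 and 1307. These point to a structure of the samples: the highest for TRD put the 3 trabectedin arrays of slide 1 with the 3 mafosfamide arrays of slide 2, while the highest for TRAIL put those of slide 1 with 3 arrays of slide 3 and so cuts that slide. Between trabectedin and doxorubicin 1 of 35 splits, the real one, gave 14105 genes, and the highest other gave 1. That split follows the slides exactly, so it cannot tell the drugs from the slides. Between doxorubicin and mafosfamide 1 of 35 splits, the real one, gave 4742, against 3728 for the highest other. In both contrasts this would exclude chance only for arrays taken as exchangeable. The splits do not take account of the slide, within which arrays correlate (0.888), and with slide as a block 0 genes passed in both contrasts. Leaving out 1 array gave 3 to 12909 genes for doxorubicin against mafosfamide. Between trabectedin and mafosfamide 2 of 35 gave 5340 or more, so chance is not excluded, and 8911 came from the split that puts the 3 trabectedin arrays of slide 1 with the array labelled mafosfamide+TRD+TRAIL, against the 4 arrays of slide 2. For gene lists chance was not excluded in any contrast: 28 of 100 splits reached 10 lists for TRD (highest other 16) and 20 of 100 reached 12 for TRAIL (15). Between drugs 13 of 35 reached 9 (13), 16 of 35 reached 11 (14) and 26 of 35 reached 5 (13).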

How the results depend on the processing

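The settings with slide and channel as a block, with the doxorubicin arrays only, and for the doxorubicin pairs were chosen after the data were seen. Of the values of single genes over all settings, those included, 3162 were counted as unchanged, 1217 lost the threshold, 18 gained it, 149 moved and 132 turned sign. For genes past the threshold, unchanged means the same direction and side of it. For other genes it means a shift under the SD of that gene between arrays. Among tested genes not past the threshold, that can include a turn of sign. Of the counts of genes and of gene lists, 280 stayed within 1.5 times and 122 did not. Genes changed by TRD and by TRAIL stayed at 0 under every alternative run with limma, including the doxorubicin arrays alone, where no simulated gene was recovered either, and the cause of the changes below was not tested. Signal over background limits the dim genes, and the number of arrays limits all.

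Slide as a block left 0, 1 and 0 genes for trabectedin against doxorubicin, trabectedin against mafosfamide and doxorubicin against mafosfamide, and so did slide and channel as a block. Slide as a random block left 0, 0 and 3. The blocked drug contrasts rest on the 2 arrays whose drug spans slides, those labelled trabectedin+TRD+TRAIL and mafosfamide+TRD+TRAIL. TRD between drugs went from 0 to 858 genes with slide as a block, 279 with slide and channel, 246 with a random block, 2 with normexp, 3 without a filter and 1 among genes above background on all 12 arrays. TRAIL between drugs had 1 with a random block, and TRD with TRAIL had 10 with slide and channel. Doxorubicin against mafosfamide gave 12694 genes with normexp. Gene lists with slide as a block numbered 3 for TRD, 4 for TRAIL, 5 for trabectedin against doxorubicin and 7 for trabectedin against mafosfamide, and with slide and channel 1, 4 and 5 for TRD, TRAIL and trabectedin against doxorubicin. normexp gave 15 lists for trabectedin against doxorubicin and 11 for doxorubicin against mafosfamide. The doxorubicin arrays only gave 6 for TRD and 4 for TRAIL. In camera with an estimated correlation none of these passed (adjusted p = 0.880 or above for TRD and 0.924 or above for TRAIL). With the doxorubicin arrays only, that version rests on 1 residual degree of freedom, so it cannot decide. An estimated correlation gave 0 in all 5 contrasts, and fry gave 0 for TRD, 0 for TRAIL, 7 for trabectedin against mafosfamide and 3 for doxorubicin against mafosfamide. camera with a random block was not run.

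Leaving out each array gave 8 to 14 for gene lists changed by TRAIL, 1 to 13 for gene lists changed by TRD, 4 to 7 for gene lists differing between doxorubicin and mafosfamide, 7 to 11 for gene lists differing between trabectedin and doxorubicin, 8 to 13 for gene lists differing between trabectedin and mafosfamide, 0 to 0 for genes changed by TRAIL, 0 to 0 for genes changed by TRD, 3 to 12909 for genes differing between doxorubicin and mafosfamide, 10905 to 16167 for genes differing between trabectedin and doxorubicin, 0 to 12136 for genes differing between trabectedin and mafosfamide, 0 to 1474 for genes whose TRAIL effect differs between drugs, 0 to 3342 for genes whose TRD effect differs between drugs, 0 to 91 for genes with a TRD by TRAIL interaction.

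For TRD, the genes of like direction in both doxorubicin pairs numbered 166 with normexp, 1419 at 1.5-fold and 72 at 4-fold. For TRAIL they numbered 0 with normexp, 2 with quantile normalisation, 45 without a filter, 22 at 1.5-fold and 0 at 4-fold. With normexp the median of all genes was -0.17 and 0.19 in these pairs, against 0.0128 and 0.0431 in the main analysis, while the NF-kB and p53 lists stayed below it in both.

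Counts against the control that moved with normexp were 8480 (trabectedin), 8232 (trabectedin+TRD), 8679 (trabectedin+TRAIL), 5320 (trabectedin+TRD+TRAIL), 124 (doxorubicin), 458 (doxorubicin+TRD), 406 (doxorubicin+TRAIL), 636 (doxorubicin+TRD+TRAIL), 5740 (mafosfamide), 5164 (mafosfamide+TRD), 5661 (mafosfamide+TRAIL), 331 (mafosfamide+TRD+TRAIL). Counts against the control that moved among genes above background on all 12 arrays were 8997 (trabectedin), 8740 (trabectedin+TRD), 8990 (trabectedin+TRAIL), 6163 (trabectedin+TRD+TRAIL), 262 (doxorubicin), 387 (doxorubicin+TRD), 301 (doxorubicin+TRAIL), 522 (doxorubicin+TRD+TRAIL), 6429 (mafosfamide), 5926 (mafosfamide+TRD), 6433 (mafosfamide+TRAIL), 731 (mafosfamide+TRD+TRAIL). Counts against the control that moved at 4-fold were 6884 (trabectedin), 6647 (trabectedin+TRD), 6918 (trabectedin+TRAIL), 4624 (trabectedin+TRD+TRAIL), 247 (doxorubicin), 157 (doxorubicin+TRD), 339 (doxorubicin+TRAIL), 410 (doxorubicin+TRD+TRAIL), 4821 (mafosfamide), 4537 (mafosfamide+TRD), 4844 (mafosfamide+TRAIL), 571 (mafosfamide+TRD+TRAIL). Counts against the control that moved without a filter were 1779 (doxorubicin), 1553 (doxorubicin+TRD), 1889 (doxorubicin+TRAIL), 2398 (doxorubicin+TRD+TRAIL), 2725 (mafosfamide+TRD+TRAIL). Counts against the control that moved at 1.5-fold were 2368 (doxorubicin), 2605 (doxorubicin+TRD), 2646 (doxorubicin+TRAIL), 3740 (doxorubicin+TRD+TRAIL), 3779 (mafosfamide+TRD+TRAIL).

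With slide as a block, 61 named gene values turned sign. For trabectedin against doxorubicin they were KRT23 -0.0569, DUSP23 -0.93, VIL1 -1.48, LAD1 -1.22, SELENBP1 -0.998, TSPAN8 -0.21, PTX3 0.36, ARMCX1 0.26, PDGFC 0.84, ANTXR1 0.16, TNFRSF10A -0.81, CASP8 -0.41, CFLAR -0.68, CCNE2 0.90, PRIM1 0.31, RRM2 0.42, CDC45 0.55, LOX 0.0728, MMP3 1.39, SPARC 2.85, CCNA2 0.54, PLK1 0.68, KIF11 0.22, HSPB1 -0.19, HSPA1A 2.22, SERPINH1 0.44, BNIP3 0.37, ENO2 0.28, CXCL11 -2.31, IRF7 -0.70, CDH1 -0.77, PLK2 0.40, GADD45A 1.29. For trabectedin against mafosfamide they were STYXL2 -0.72, TSPAN8 -1.57, REG4 -0.29, HDGFL3 0.44, CALD1 0.21, LHFPL6 0.75, ANTXR1 0.45, GNG11 1.44, MSN 0.33, RRM2 0.30, PRIM1 0.27, MCM4 0.0607, COL6A1 0.23, CCNA2 0.37, KIF20A 0.19, CENPE 0.11, SERPINH1 0.0675, HSPH1 0.0772, ANKRD37 0.14, LDHA 0.22, CXCL11 -1.97, MT1M 0.18, MT1E 0.0535. For doxorubicin against mafosfamide they were GPC6 -0.0806, CCBE1 -0.0644, TNFRSF10A 0.23, CFLAR 0.15, MMP3 -0.48.

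With slide and channel as a block, 63 named gene values turned sign. For trabectedin against doxorubicin they were DUSP23 -0.72, VIL1 -0.17, LAD1 -1.60, CEP15 0.0729, TGFB2 0.78, ARMCX1 0.72, ANTXR1 0.0938, BCAT1 0.0906, TNFRSF10A -0.31, CASP8 -1.31, CFLAR -1.66, PRIM1 0.87, RRM2 0.0193, CDC45 0.12, LOX 0.70, MMP3 2.29, SPARC 1.15, CCNA2 0.56, CENPE 0.0368, PLK1 0.73, KIF11 0.096, HSPA1A 1.39, BNIP3 0.21, ENO2 0.77, CXCL11 -4.53, IRF7 -1.59, CDH1 -0.13, MT1E 0.13, GADD45A 1.04. For trabectedin against mafosfamide they were STYXL2 -0.97, TSPAN8 -1.25, REG4 -0.31, HDGFL3 0.57, CALD1 0.16, LHFPL6 0.53, ANTXR1 0.43, GNG11 1.38, MSN 0.20, RRM2 0.19, PRIM1 0.42, MCM4 0.0138, COL6A1 0.12, CCNA2 0.37, KIF20A 0.27, CENPE 0.13, ANKRD37 0.61, ENO2 0.0561, LDHA 0.16, PSAT1 0.0435, CXCL11 -2.58, MT1M 0.15, MT1E 0.11. For doxorubicin against mafosfamide they included CEP15 -0.0776, SCG5 -0.31, GPC6 -0.73, CCBE1 -0.97, GSDME -0.00429, TRIM15 0.77, CFLAR 0.86, SQLE 0.18, MMP3 -1.13, LOX -0.40.

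With slide as a random block, 8 named gene values turned sign. For trabectedin against doxorubicin they were CFLAR -0.0629, SPARC 1.02, PLK1 0.23, HSPA1A 0.81, GADD45A 0.57. For trabectedin against mafosfamide they were GNG11 0.25, CCNA2 0.0314, CXCL11 -0.38.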

Other observations

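All tests of this part were chosen after the data were seen. Zinc finger genes were frequent among those lower with TRD on the doxorubicin arrays: 52 of 393 measured genes whose symbol begins with ZNF were at least 2-fold lower in both pairs, against 198 of 13616 other named genes (odds ratio 10.3, Fisher's exact test, two-sided p = 1.02e-30, genes not being independent). ZNF443 (-3.41 and -3.06) and ZNF57 (-3.39 and -2.30) were among them. SKIDA1 (-4.26 and -3.38), RNASE4 (-2.86 and -4.44), TENT5A (-3.02 and -2.78) and BMP2 (-2.74 and -2.94) were lower in both pairs. NME8 (2.28 and 3.49), CCR1 (2.68 and 2.06) and FUT1 (1.91 and 2.29) were higher. SKIDA1, RNASE4, ZNF443, ZNF57, CCR1 and FUT1, and NME8 in the second pair, lay below background on their lower side, so their differences are no exact sizes.

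On slide 3, samples read from 1 array shared genes that stood above the other samples of that slide. Genes at least 3 log2 units above the other 4 samples of slide 3 in both numbered 13 for control and doxorubicin+TRD, 49 for doxorubicin and doxorubicin+TRD+TRAIL, and 69 for doxorubicin+TRAIL and mafosfamide+TRD+TRAIL. The 12 other pairs of slide 3 had 0. Examples were NCKAP1L and GIMAP8.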
